A study of Mus musculus with 2 samples.

How the data were processed

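Total RNA of bEnd3 cells that had received an siRNA against Smad4 or a control siRNA by retrovirus was hybridised to Affymetrix mouse arrays, with 2 infections pooled per group, per the labels. The groups were taken from the sample titles, which gave 1 array each. The deposited values are probe set signal intensity on a linear scale, made with MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and detection calls are not given in the sources used here, and the maker's standard labelling of cRNA was followed, per the labels' protocols. The deposited table held 45101 probe sets, of which 64 control probe sets were left out of gene comparisons, leaving 45037. All values were above 0 (lowest 0.0110) and reached 9783 on the array labelled Smad4-siRNA and 9247 on the Control-siRNA array, with medians of 24.8 and 21.0.

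Gene names came from the platform annotation supplied with the table, which can be old, updated by Entrez identifier against NCBI's RefSeq gene table for the GRCm38.p6 assembly, used only for names and for the order of neighbouring genes. In all, 34945 probe sets had 1 gene, 932 had several and were given no gene, and 9160 were unnamed here. The 34945 stood for 18194 genes, of which 18032 matched the RefSeq table.

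Except where stated, choices in this and the next paragraph were fixed before the data were examined. The values were to be used as deposited if the 2% trimmed means of the arrays differed by under 5%. The means were 115 and 138, a difference of -17.2%, so the log2 signals were quantile normalized. In place of detection calls, each array's median (22.8 after normalization) served as a floor. A gene was represented by its probe set of highest mean log2 signal. It counted as measured on both arrays if both signals were at or above the floor. With 1 side below it, the ratio of the bright signal to the floor is given as a bound ("at least N-fold"), and no fold is given where both were below. Log2 ratios are the array labelled Smad4-siRNA minus the Control-siRNA array. With 1 array per group no test between groups was made, and counts of 2-fold differences describe these arrays. The SD between probe sets of a gene served as technical error, and holds no error that all probe sets of a gene share.

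Gene lists were 21 groups of pathway, endothelial and metabolic genes and 6 groups of markers of other cells (pericyte and smooth muscle, fibroblast, astrocyte, microglia and leukocyte, neuron and oligodendrocyte, epithelial). A list's median log2 ratio was taken over genes with at least 1 side at or above the floor, and set against 10000 random lists of the same size drawn from 20 bins of mean signal (seed 1). The percentile describes these arrays and is not a p-value. A list stood apart if its median lay outside the central 95% of the random medians, as 5% of random lists do. Medians are also given with every side below the floor raised to it, but the random medians were not recomputed in this way. There were 47 genes on more than 1 list. The genes named were Smad4 and Cdh2, and the 15 highest and 15 lowest log2 ratios among genes measured on both arrays. In the highest and lowest genes, all probe sets measured on both arrays had to have the same sign. Most had only 1 such probe set, as Cp did (1 of 8), and met this without a check. Also named were the 5 largest bounds each way with the bright side at least 4 times the floor. To these were added the 3 members of each list measured on both arrays farthest from 0 (described in part), and genes with known roles beside Smad4 in endothelium. Outside this rule, and chosen after their values were seen, are the sex-linked genes, Vim, Actb, Pecam1, Cldn5, Dcn, Fbln1, Mmp2, Col4a1, Col4a2, Ctnnb1, Zeb1, Pgk1, Lrp1, Plvap, Thbd, Klf2, Tek, Cdkn2b, Jun and the families of the closing part.

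Alternatives were the values as deposited, centring of log2 ratios on their median, removal of a lowess trend on signal (fraction 0.3), a floor at the 25th or 75th percentile, adding the 25th percentile as a pseudocount, the median over a gene's probe sets, leaving out probe sets with suffixes for shared sequence, and random lists not matched on signal. After the data were seen, lists without the genes that another list also holds were added. The gene comparison was tested on simulated data made from the Control-siRNA array, with 18194 genes of which 200, all drawn from those at least 16 times the floor, were changed, and with noise of SD 0.3 on the log2 scale. It recovered 90.0% of genes changed 2.83-fold, 94.0% of those changed 4-fold and 100% of those changed 8-fold or 16-fold, each over 50 genes, and called 1.73% of unchanged genes. A list of 20 genes shifted by 2-fold came out at a median of 0.99, and 5.50% of 200 unshifted lists stood apart. The share of unchanged genes called follows largely from the noise that was set. With only 200 genes changed, the simulation cannot show how the normalization behaves on arrays that differ as widely as these.

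Hybridisation spikes, bacterial and phage transcripts added at fixed amounts, had a mean log2 ratio of 0.11 as deposited (SD 0.09 over 18 probe sets). Poly-A spikes, added to the RNA, had one of 0.24 (SD 0.20 over 24 probe sets), leaving out 3 trpn probe sets. These 3 were below the floor on both arrays, with log2 ratios of -1.68, 0.85 and -0.25. The ratio of the 3' to the 5' control probe set was 1.48 and 1.23 for Actb and 0.657 and 0.653 for Gapdh on the array labelled Smad4-siRNA and the Control-siRNA array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.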

Results

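Transcript levels were measured in bEnd3 cells, a mouse endothelial line from brain microvessels that carries polyoma middle T antigen, after retroviral delivery of an siRNA against Smad4 or of a control siRNA and selection with puromycin. Smad4 is the common partner of the receptor-activated Smads in TGF-β and BMP signalling, and the comparison asks which transcripts of brain endothelial cells depend on it. Each group had 1 Affymetrix array, hybridised with RNA pooled from 2 infections. There were thus no replicates, no difference between the arrays has a replicate check, and the number of arrays limits the precision of every value. As a technical error for single genes, the log2 ratios of different probe sets of a gene had a pooled SD of 0.47 over 4546 genes. It covers the spread between probe sets only, not that between arrays or cultures. Of 18194 genes with a probe set of their own, 9479 were at or above the floor on both arrays. A further 1093 were measured only on the array labelled Smad4-siRNA, 1009 only on the Control-siRNA array, and 6613 on neither.

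The targeted transcript was not lower on the array labelled Smad4-siRNA. The brightest of the 3 Smad4 probe sets had a quantile-normalized signal of 1165 there and 916 on the Control-siRNA array, a log2 ratio of 0.35, which was -0.07 for the values as deposited. The other probe sets had log2 ratios of 0.25 and 0.58 after normalization and of -0.12 and 0.21 as deposited. Because Smad4 mRNA did not show the fall that the label implies, the sample is called the array labelled Smad4-siRNA throughout. Below, "higher" and "lower" state the direction on that array relative to the Control-siRNA array, not a response to Smad4 depletion. Cdh2, which encodes N-cadherin, was 1.56-fold lower by its brightest probe set, with log2 ratios of -0.64 and -0.55 for its probe sets and of -0.87 and -0.61 as deposited.

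Genes of the sex chromosomes, looked at after their values were seen, also differed between the arrays. Xist, the RNA that silences an X chromosome in female cells, had a signal of 4476 on the array labelled Smad4-siRNA and of 20.7, below the floor of 22.8, on the Control-siRNA array. All 3 of its probe sets showed this. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 324, 122 and 112 on the Control-siRNA array and of 0.349, 4.69 and 4.03, all below the floor, on the array labelled Smad4-siRNA. Vim and Actb, cytoskeletal genes of most cultured cells, had log2 ratios of -0.12 and -0.33.

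**Figure D1:**
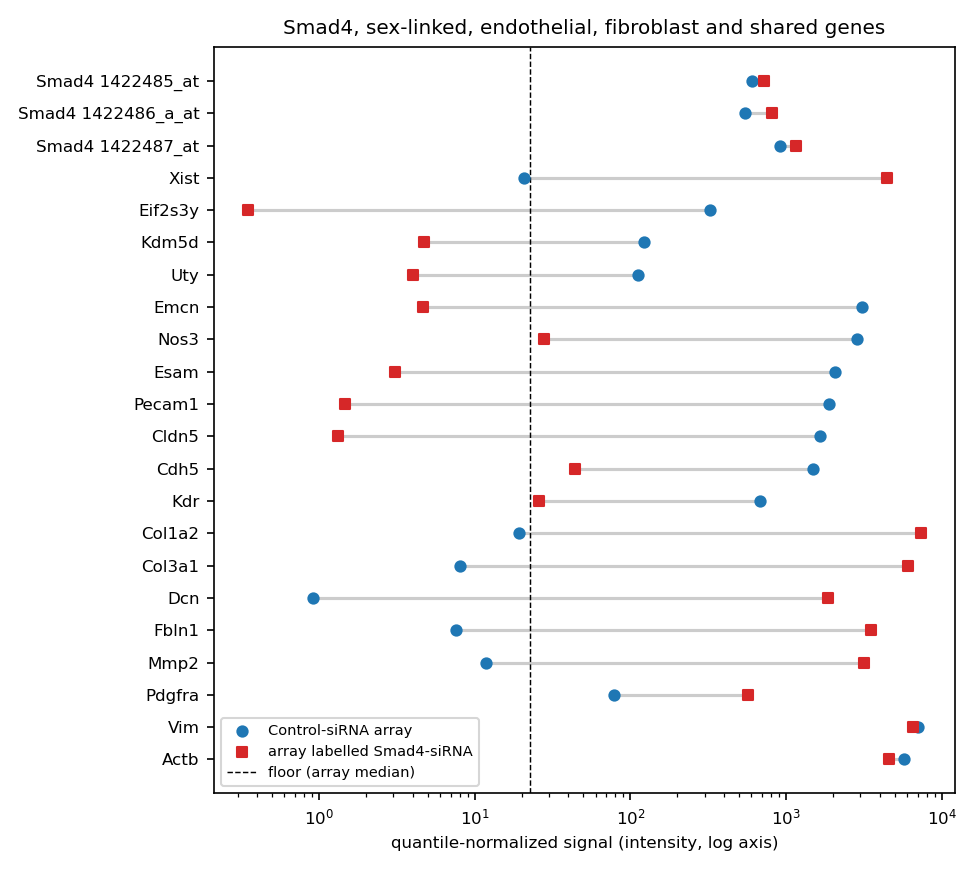
Quantile-normalized signal (intensity, log axis) on the array labelled Smad4-siRNA (squares) and on the Control-siRNA array (circles), with 1 array per group and no error bars, for the 3 Smad4 probe sets and for sex-linked, endothelial, fibroblast and shared genes. The Smad4 pairs lie close together, with 1165 against 916 for the brightest, while Xist and the fibroblast genes are bright only on the array labelled Smad4-siRNA, except Pdgfra at 570 against 78.8, and the endothelial and Y-linked genes are bright only on the Control-siRNA array; the dashed line is the floor of 22.8.

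The arrays differed widely. Among the genes measured on both, 1196 were at least 2-fold higher and 1426 at least 2-fold lower on the array labelled Smad4-siRNA, together 27.7%, and 6857 lay within 2-fold. For the values as deposited the counts were 1023 and 1957, so that the higher genes made up 34.3% of these calls in place of 45.6%. Centring on the median gave 1392 higher and 1146 lower (54.8%) and removal of a lowess trend 1358 and 1179 (53.5%), so which direction held more genes depended on the scaling. The scaling moved the median log2 ratio of all measured genes, which was -0.15 after quantile normalization and -0.33 as deposited. At least 8-fold differences were found for 133 higher and 62 lower genes. Of the genes measured on 1 array only, 654 had a bound of at least 2-fold higher and 400 of at least 2-fold lower. Over all probe sets, the log2 signals of the arrays had a Pearson correlation of 0.823, which is across probe sets that are not independent replicates.

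Ceruloplasmin (Cp), a copper-carrying ferroxidase, was 226-fold higher, and the metal-binding metallothioneins Mt1 and Mt2 were 124-fold and 95.9-fold higher. Next came the matrix glycoprotein Fbln2 (78.7-fold), Itm2a (68.8-fold), the collagenase Mmp13 (63.5-fold), the lipid carrier Apoe (59.0-fold), Basp1 (56.6-fold), Gstm2 (52.6-fold), the oncostatin M receptor Osmr (50.6-fold), Enah (49.9-fold), the smooth muscle actin Acta2 (48.8-fold), Nsg1 (44.2-fold), Itgb5 (40.8-fold) and Gsta4 (38.8-fold). At the other end, the endothelial nitric oxide synthase Nos3 was 102-fold lower, Igfbp3 87.8-fold, Ctla2b 63.5-fold, Ramp2 59.8-fold, the endothelial phosphatase Ptprb 38.3-fold, the peptide hormone Apln 36.9-fold and the Notch regulator Nrarp 36.7-fold. The VE-cadherin gene Cdh5 was 34.0-fold lower, Upp1 31.7-fold, Cd34 30.4-fold, Sorbs2 26.5-fold, Ecscr 26.2-fold, the VEGF receptor Kdr 26.1-fold, Itga6 25.4-fold and Arap3 23.3-fold. Among genes below the floor on 1 array, the largest bounds were at least 324-fold higher for Col1a2, 275-fold for Bgn, 265-fold for Col3a1, 239-fold for Ifitm1 and 231-fold for Mgp, and at least 136-fold lower for Emcn, 126-fold for AA467197, 101-fold for Srgn, 90.2-fold for Esam and 90.0-fold for Cd93.

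**Figure D2:**
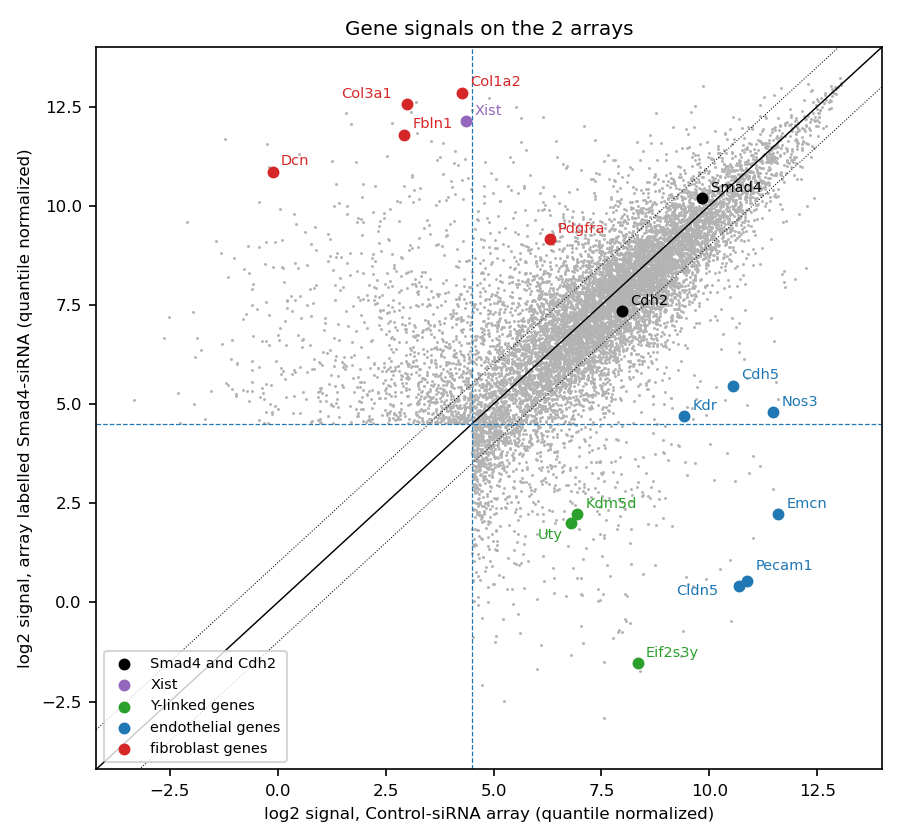
Quantile-normalized log2 signal of each gene measured on at least 1 array, with the Control-siRNA array on the x axis and the array labelled Smad4-siRNA on the y axis; the solid line marks equal signal, dotted lines 2-fold differences and dashed lines the floor. Smad4 and Cdh2 lie within the dotted lines, whereas Emcn, Pecam1 and Cldn5 fall below the floor of the array labelled Smad4-siRNA, and Col1a2, Col3a1, Fbln1, Dcn and Xist below that of the Control-siRNA array.

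Genes that define endothelial cells were nearly all lower. Of the 31 endothelial identity genes measured, all of which reached the floor on the Control-siRNA array, 28 were at least 2-fold lower, 0 were at least 2-fold higher and 3 lay between. These 3 were measured on both arrays, but in later counts "between" also holds genes with a bound under 2-fold. The difference of such genes may be larger than 2-fold. Only 13 of them reached the floor on the array labelled Smad4-siRNA. Nos3, Ramp2 and Cdh5 were lower by the folds given above. Pecam1 and Cldn5, named after their values were seen, encode an adhesion molecule and a tight junction protein of endothelium and were at least 82.8-fold and 72.2-fold lower. Eng, the endothelial co-receptor for BMP ligands, had log2 ratios of -0.56 and -1.90 in its probe sets. The list median was -5.31 (-3.83 with unmeasured sides set to the floor), below all of 10000 random lists matched on signal. Of these genes, Tek also lies in a run of 8 neighbouring genes that were all below the floor on the array labelled Smad4-siRNA.

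Junction genes were lower as a group, and Notch and vessel-type genes were so in part of the settings. Among 24 cell-cell junction genes, 11 were at least 2-fold lower, 0 at least 2-fold higher and 13 between, of which 10 were measured on both arrays. The others, Cldn1, Cgn and Gja4, were below the floor on the Control-siRNA array and were higher by bounds under 2-fold. Ptprb, Cdh5 and Cdh13 (7.34-fold) were farthest from 0 among those measured on both arrays, while Esam, Pecam1 and Cldn5 had larger bounds. The list median was -0.80, at a percentile of 0.210. The gene for β-catenin, which binds VE-cadherin, was within 2-fold, as Ctnnb1 had a log2 ratio of -0.21 in its brightest probe set and both signs among its probe sets. Of 21 Notch pathway genes, 9 were lower, 4 higher and 8 between, of which 6 were measured on both arrays. Nrarp, the ligand Dll1 (15.2-fold) and the receptor Notch1 (4.45-fold) were lower, Notch4 was at least 18.9-fold lower and Hey1 at least 2.14-fold lower, whereas Hes1 had a log2 ratio of -0.14. The Notch median of -1.22 was -0.31 with unmeasured sides set to the floor. The central 95% of random medians ran from -0.66 to 0.49. Those medians used ratios without sides set to the floor, so they cannot decide whether the value of -0.31 stands apart. With a floor at the 75th percentile the Notch median was -0.0593 and no longer stood apart. Of 13 arterial, venous and lymphatic markers, 7 were lower, 2 higher and 4 between, with Nrp2 8.39-fold and Ephb4 3.72-fold lower and Unc5b 2.78-fold higher. Their median of -1.89 (-1.10 with bounds) turned to 0.15 without suffixed probe sets and without genes on another list (3 genes left), and with a floor at the 75th percentile it was -0.87 and no longer stood apart. Beside these groups, 9 of 11 fibroblast markers were at least 2-fold higher.

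Fibroblast and matrix genes were higher in most cases, and most of the fibroblast markers were below the floor on the Control-siRNA array. All 11 measured fibroblast markers reached the floor on the array labelled Smad4-siRNA and 2 of them, Pdgfra and S100a4, on the Control-siRNA array. Besides the 9 that were at least 2-fold higher, 0 were lower and 2 lay between, of which 1 was measured on both arrays. The collagen genes Col1a2 and Col3a1 had signals of 7389 and 6046. Dcn, a matrix proteoglycan named after its values were seen, was at least 81.7-fold higher, and the PDGF receptor Pdgfra 7.24-fold higher, whereas S100a4 had a log2 ratio of 0.09 and of -0.31 as deposited. The list median was 7.24 (5.18 with bounds). Of 32 extracellular matrix genes, 24 were higher, 1 was lower and 7 lay between, with Col8a1 20.3-fold and Col5a1 14.6-fold higher and a median of 3.47 (2.76 with bounds). The basement membrane collagen genes Col4a1 and Col4a2 had log2 ratios of -0.77 and -0.33.

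Mesenchymal factors and pericyte markers were mostly higher too. Of 16 mesenchymal transition genes, 10 were higher, 0 lower and 6 between. Acta2 and the forkhead factors Foxc1 (26.9-fold) and Foxc2 (6.23-fold) led among those measured on both arrays. Twist1, below the floor on the Control-siRNA array, was at least 33.7-fold higher, and Zeb1 had a log2 ratio of -0.01. The median was 2.45 (2.04 with bounds). Of 8 pericyte and smooth muscle markers, 7 were higher, 0 were lower and 1 had a bound under 2-fold, with a median of 5.14 (3.03 with bounds). Of 4 measured astrocyte markers (median 3.88, or 2.06 with bounds), 3 were higher and below the floor on the Control-siRNA array, and the other, Gja1, had a log2 ratio of 0.59 in its brightest probe set and both signs among its probe sets. These medians exceeded those of 99.6% or more of random lists, but with a floor at the 75th percentile the pericyte (5.73) and astrocyte (4.83) markers no longer stood apart, nor did the astrocyte markers with one at the 25th (0.59) or without suffixed probe sets (2.93). The astrocyte median with bounds lay below the 2.53 that the central 95% of random medians reached. Those medians used ratios without bounds, so the 2 are unlike measures. Microglia and leukocyte markers (4 genes, median -0.52, with Cd68 23.3-fold lower) and neuron and oligodendrocyte markers (3 genes, median 0.31, or 0.27 with bounds) did not stand apart, and only 2 epithelial markers were measured, too few for a median.

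Target genes of TGF-β and BMP signalling, which Smad4 complexes activate, were not lower as a group. Of 19 measured, 7 were at least 2-fold higher, 4 lower and 8 between. Id3 was 4.39-fold, the inhibitory Smad gene Smad6 3.98-fold, Smad7 2.10-fold and Id1 2.07-fold higher, and these were also above 0 as deposited (log2 ratios of 1.79, 1.92, 0.95 and 0.69). Id2 had a log2 ratio of -0.59, Tgif1 was 2.83-fold lower, and Cdkn2b, a member of the run of neighbouring genes that holds Tek, was at least 42.6-fold lower. The list median was 0.58 at a percentile of 99.0, but 0.21 as deposited, where it did not stand apart. Ligands, receptors and Smads of the pathway went both ways, with 6 higher, 5 lower and 14 between among 25 genes and a median of 0.27 that did not stand apart. Bmpr1a was 25.8-fold and Tgfbr3 19.1-fold higher and Tgfb1 5.34-fold lower. Tgfbr1 and Tgfbr2 had log2 ratios of 0.27 and 0.44 (-0.02 and 0.06 as deposited), and Acvrl1 of 0.35 and -0.92 in its probe sets. On the same arrays the endothelial list had a median of -5.31 (-3.83 with bounds).

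Interferon response genes were mostly higher, and inflammatory genes were higher more often than lower. Of 28 interferon response genes, 19 were higher, 1 lower and 8 between, with the immunoproteasome subunit Psmb8 10.6-fold, the RNA sensor Ifih1 8.49-fold and Gbp2 7.59-fold higher and a median of 1.73 (1.65 with bounds). Of 22 leukocyte adhesion and inflammation genes, 10 were higher, 4 lower and 8 between, of which 5 were measured on both arrays. The cytokine gene Il6 was 24.7-fold and Cx3cl1 9.75-fold higher, whereas the endothelial adhesion gene Selp was 13.1-fold lower, and the median was 1.36 (0.79 with bounds). Both medians lay above all of the random lists, and both stood beside fibroblast markers that were higher.

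Cell cycle genes were higher too. Of 31 proliferation genes, 20 were higher, 0 lower and 11 between, with Top2a 7.53-fold, Mki67 5.93-fold and Cenpa 5.86-fold higher and a median of 1.33, above all random lists. The 20 p53 targets and Cdk inhibitors split into 6 higher, 1 lower and 13 between (median 0.68, percentile 99.7), with the inhibitor genes Cdkn1b 4.33-fold, Cdkn1c 3.96-fold and the stress gene Sesn1 3.88-fold higher. Immediate early and YAP/SRF target genes went both ways, with 8 higher, 7 lower and 11 between and a median of -0.19. Fos (35.7-fold), Egr1 (19.8-fold) and Axl (18.0-fold) were higher, whereas Jun, in the run of neighbouring genes named above, was at least 16.2-fold lower. Of 11 Wnt targets, 1 was higher, 5 were lower and 5 lay between (median -0.71, or -0.10 with bounds), with Fzd4 5.89-fold, Ccnd1 4.81-fold and Myc 3.23-fold lower. Of the 5 between, 2 were measured on both arrays. Neither of the last lists stood apart, but with a floor at the 75th percentile both did, the immediate early and YAP/SRF targets with a median of 0.43, opposite in sign, and the Wnt targets with -1.98. Fibroblast markers, with 9 of 11 higher, went the same way as the cell cycle genes, but with 1 array per group this shows no link.

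Genes of lipid and sugar metabolism differed in the same direction. Of 19 genes on the cholesterol synthesis list, which also holds fatty acid genes, 16 were higher, 0 lower and 3 between (median 1.74), with the fatty acid desaturase Scd1 10.2-fold and, among sterol enzymes, the isomerase Idi1 8.09-fold and the synthase Hmgcs1 6.82-fold higher. Of 23 glycolysis and hypoxia genes, 13 were higher, 0 lower and 10 between (median 1.21). Among those measured on both arrays, Bnip3 (12.4-fold), the hexokinase Hk2 (9.20-fold) and Pfkp (6.91-fold) led, while Pgk1 had a log2 ratio of 0.07 and of -0.06 as deposited. Both medians were above all random lists, on arrays whose endothelial genes had a median of -5.31 (-3.83 with bounds). The 20 unfolded protein and amino acid stress genes did not stand apart (median -0.18, 3 higher, 4 lower, 13 between), with Chac1 3.27-fold and Trib3 3.21-fold lower and Slc7a11 3.17-fold higher.

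In several groups large differences in opposite directions left a median near 0. Among 28 angiogenic factors and guidance receptors, 13 were higher, 12 lower and 3 between (median 0.28), with Angptl4 (log2 ratio 4.33) and Angpt2 (18.0-fold) higher, Apln 36.9-fold lower and Pdgfb at least 5.25-fold lower. This median stood apart in several alternatives, being 0.85 with a floor at the 25th percentile and 0.88 without suffixed probe sets. The 18 matrix proteases and inhibitors had a median of 0.08, with Mmp13 63.5-fold and Mmp14 27.9-fold higher and the urokinase receptor gene Plaur 20.8-fold lower (6 higher, 5 lower, 7 between). The 11 integrins had a median of 0.38, with Itgb5 40.8-fold higher and Itga6 25.4-fold and Itga3 6.62-fold lower (3 higher, 3 lower, 5 between). Of 19 blood-brain barrier transport genes, 5 were higher, 6 lower and 8 between (median -0.49), with the caveolin gene Cav1 4.80-fold, Lrp8 4.62-fold and the efflux pump gene Abcb1b 4.29-fold lower. Among its genes below the floor on 1 array, and named after their values were seen, Lrp1 was at least 69.2-fold higher and Plvap at least 68.3-fold lower. In all, 16 of 26 lists stood apart, 12 of them higher and 4 lower, where lists of randomly drawn genes give 1.3. The genes of these lists were chosen as related and some are shared, so 1.3 is not a chance level for them.

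**Figure D3:**
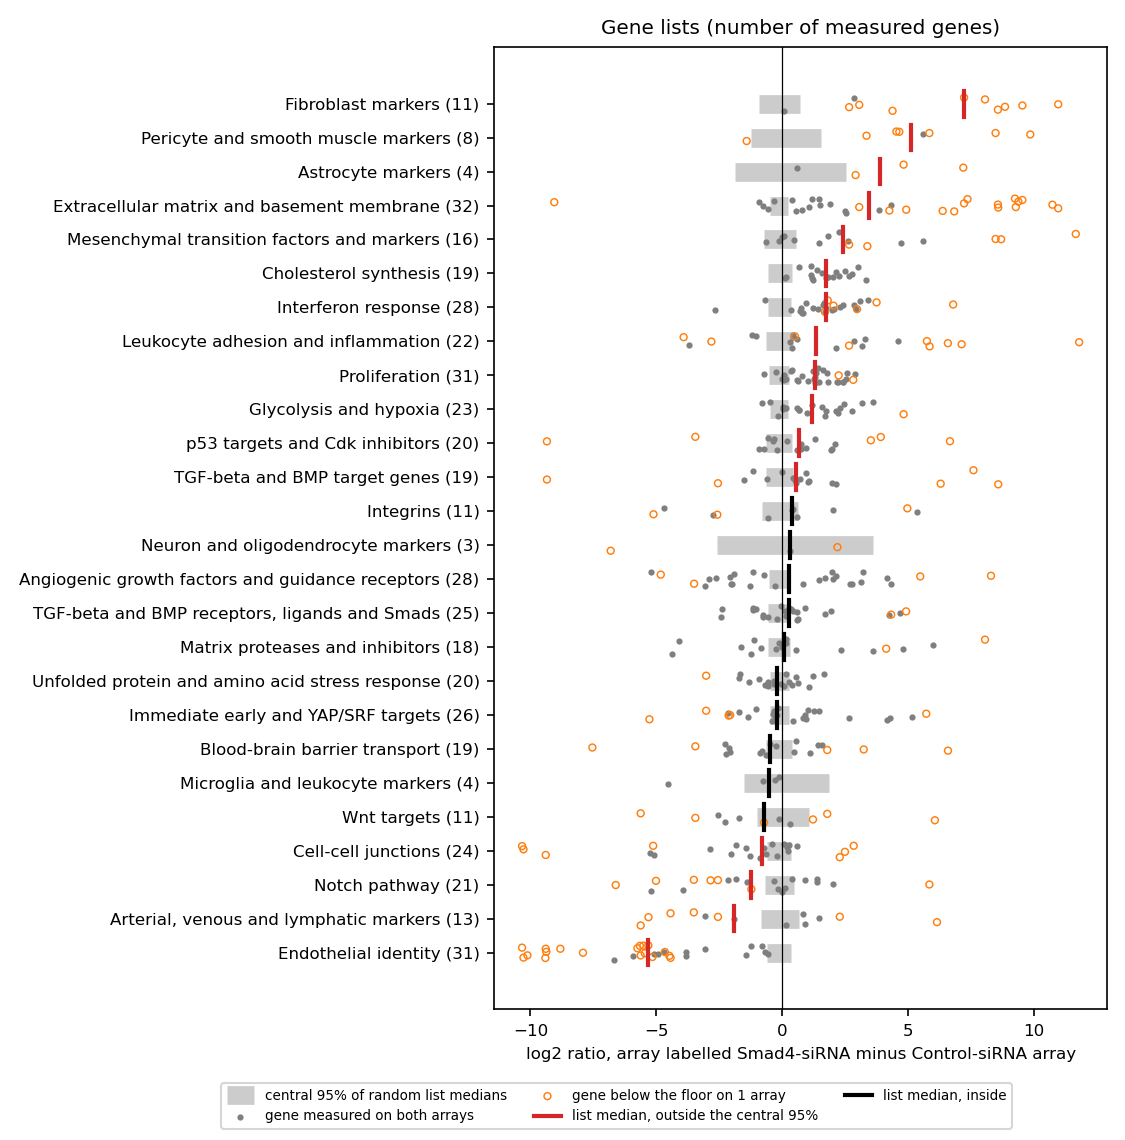
Log2 ratio (array labelled Smad4-siRNA minus Control-siRNA array, quantile normalized) of each gene in 26 lists, with the number of measured genes in brackets, genes below the floor on 1 array as open circles at their measured ratio, list medians as bars and the central 95% of medians of 10000 matched random lists in grey. Fibroblast markers, at a median of 7.24, and endothelial identity genes, at -5.31, lie at the ends.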

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

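All tests in this part were chosen after the results were seen. Probe sets outside the gene comparison also differed between the arrays. Of 9160 unnamed probe sets, 85 were at least 4 times the floor on the array labelled Smad4-siRNA and below it on the Control-siRNA array, and 16 the other way round. A control probe set for the 3' end of mouse pyruvate carboxylase, an enzyme of mitochondria, had a deposited signal of 113 on the array labelled Smad4-siRNA and of 21.8 on the Control-siRNA array.

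The pattern weighed here is the low signal of endothelial genes and the bright fibroblast genes on the array labelled Smad4-siRNA. A failed hybridisation or scaling is argued against by the hybridisation spikes, none of which differed by more than 0.26 on the log2 scale. A mixture that kept 10% or more of the Control-siRNA cells' RNA is argued against by 13 abundant endothelial genes, which kept a median of at most 1.89% of their signal, since values below the floor were raised to it, although Klf2 kept 12.1% and Thbd 58.4%. A lasting fall of Smad4 mRNA in the same cells is argued against by the Smad4 probe sets, whose lowest mean log2 ratio over 4 scalings was 0.00679, and the highest, 0.53, is small for swapped groups but does not exclude them. The median bound for Eif2s3y, Kdm5d and Uty was -2.42, with Xist bright only on the array labelled Smad4-siRNA. RNA of other cells, lacking Y-linked transcripts, on that array could give this. The type of such cells was not settled, as 9 of 11 fibroblast markers and 7 of 8 pericyte and smooth muscle markers were higher. Any effect of Smad4 siRNA within such cells stays open.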

How the results depend on the processing

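With 1 array per group no sample could be left out. The alternative with lists freed of shared genes was chosen after the data were seen. Smad4 ranged from -0.07 to 0.48 and Cdh2 from -0.87 to -0.51 over 8 alternatives. Each value lay within 0.47, the SD between probe sets, of the main value of 0.35 for Smad4 and -0.64 for Cdh2. The sign of the Smad4 ratio thus depended on the setting. The median of all measured genes shifted by -0.18 as deposited, 0.13 with centring and 0.11 with the lowess trend removed. The floor set the counts, with 1890 higher and 2164 lower genes at the 25th percentile and 469 and 592 at the 75th, since a lower floor admits more genes. Of 256 list values, 240 kept their call, and 11 of the 16 lists that stood apart did so in every alternative that gave a value. The exceptions follow, and their cause was not tested. As deposited, TGF-β and BMP targets (0.21) no longer stood apart. With the floor at the 25th percentile, astrocyte markers (0.59) no longer did and angiogenic factors (0.85) did. With the floor at the 75th percentile, Notch (-0.0593), arterial, venous and lymphatic (-0.87), pericyte (5.73) and astrocyte markers (4.83) no longer stood apart, and angiogenic factors (0.85), immediate early genes (0.43) and Wnt targets (-1.98) did. With medians over probe sets, angiogenic factors (0.34) and matrix proteases (0.31) stood apart. Without suffixed probe sets angiogenic factors (0.88) did, astrocyte markers (2.93) no longer did, and arterial, venous and lymphatic markers turned to 0.15, the value they also had without genes on another list (3 genes). Of 1779 recomputed values of 230 single genes, 204 moved by at least the SD of 0.47. None of the 230 changed the sign of a 2-fold difference. That outcome was likely beforehand, since many of these genes were named for large differences. Signals near the floor limit bounds, which understate differences of dim genes.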

Other observations

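All tests and gene families in this part were chosen after the results were seen. All 10 measured Hox genes were below the floor on 1 array. Of these, 5 were at least 2-fold lower on the array labelled Smad4-siRNA, with Hoxd8 at least 27.0-fold and Hoxd9 at least 12.9-fold lower. None was at least 2-fold higher (1 as deposited). The other 5 had a bound under 2-fold, lower for Hoxa9, Hoxb5, Hoxc6 and Hoxd10 and higher for Hoxa3, so their differences may be larger. Among 28 Fox, Tbx, Prrx and Twist genes, some of which act in mesenchyme, 16 were higher, 2 lower and 10 between (15, 4 and 9 as deposited), with bounds of at least 97.8-fold for Foxd1, 49.2-fold for Prrx1, 33.7-fold for Twist1 and 18.1-fold for Tbx18. The 7 measured Gimap genes, a clustered family of GTPases, had 5 members at least 2-fold lower and 0 higher, led by Gimap6 (at least 28.3-fold) and Gimap8 (at least 18.5-fold).

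Secreted defence and detoxification genes were higher in part. Of 10 measured complement components and regulators, 5 were higher, 1 lower and 4 between, of which C2 and Cfi had only a bound under 2-fold. Serping1, the C1 inhibitor gene, was at least 78.8-fold higher, C1s1 at least 63.7-fold and C1ra at least 47.9-fold, whereas Cd55 was 4.22-fold lower. Glutathione S-transferases split, with 7 of 14 higher, 3 lower and 4 between, of which Gstm3 had only a bound under 2-fold. Gstt1 was at least 36.0-fold higher and Gstm1 9.77-fold, but Gsto1 was 4.91-fold lower. Of 42 ribosome assembly factors and RNA polymerase I subunits, 25 were at least 2-fold lower (29 as deposited), 0 higher and 17 between. Rrp9 had a log2 ratio of -2.70, and Nhp2 was 5.88-fold, Nop56 5.06-fold and Pno1 4.99-fold lower, although the proliferation genes were higher on the same array.

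A stretch of chromosome 4 was below the floor on the array labelled Smad4-siRNA. In the gene order of the GRCm38.p6 assembly, 8659 genes had a signal at least 4 times the floor on 1 array or both. Of these, 207 were below the floor on the array labelled Smad4-siRNA, and 8 of them, Cdkn2b, Caap1, Plaa, Ift74, Tek, Mysm1, Jun and Tm2d1, followed each other without a break. Their Control-siRNA signals ranged from 159 for Ift74 to 972 for Cdkn2b. The flanking genes Mtap and Usp1 had signals of 768 and 399 on the array labelled Smad4-siRNA. The next longest run was that of 5 Gimap genes.

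Chance order is argued against, since the longest such run in 1000 random gene orders had 4 genes. A candidate explanation is loss of the segment from the genome of the cells on that array. It was tested on the 19 other genes between the ends of the run, which were too dim to take part in its choice. Of these, 4 reached the floor on the Control-siRNA array and 0 on the array labelled Smad4-siRNA, as in 0.484% (7) of 1446 overlapping windows of 19 such genes elsewhere with 4 at the floor on the Control-siRNA array. DNA was not analysed here, and silencing of the whole segment without loss stays open.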
